A study of Mus musculus with 7 samples.

How the data were processed

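RNA sequencing of mouse fetal livers at stage E12.5 was analysed in 7 libraries of 3 groups, 2 TAF10KO, 3 TAF10HET and 2 WT. Per the labels, total RNA was taken from single-cell suspensions of whole fetal livers of the C57BL/6 strain. The deposited values are whole-number read counts per Ensembl mouse gene, made by the authors, with no normalisation applied. Per the submitters' processing notes, TopHat2 2.0.8, DESeq2 and the mm10 genome build were used. The counting program, the annotation release, the strand setting and the treatment of reads that overlap several genes are not given in the sources used here. Each file held 39017 genes and 5 summary lines. The summary lines counted reads in no gene (6.81% to 10.1% of all reads counted), reads ambiguous between genes (3.98% to 5.94%) and reads that aligned to several places (14.1% to 22.25%), and all of these reads were left out of the gene counts. Reads shared by near-identical copies are therefore missing or assigned uncertainly, which bears on Hba-a1, Hba-a2, Hbb-bs, Hbb-bt, Ftl1, Aldoa, Pgk1 and Ldha. Symbols and positions came from GENCODE M21 on the same build, which matched 37693 of the gene identifiers; the 1324 unmatched ones held 0.198% of the counts.

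The counts assigned to genes ranged from 18008391 to 43401474 per library. Libraries were grouped by the genotype in their labels. Each title also carries a code of 6 digits in the form of a date. The first date code covered 1 library of each group, and the second covered 2 TAF10HET libraries, 1 WT and 1 TAF10KO library. The code was read as a day of collection shared by the livers that carry it, which the labels do not state. Before any called genes were compared, this reading was checked on the deviations of each library from its group mean. Deviations of libraries with the same date code correlated across genes at 0.40 to 0.74 in 8 pairs of libraries from different groups, and those with different codes at -0.74 to -0.40 in 8 pairs. Genes are not independent replicates, and in a group of 2 libraries the deviations mirror each other by construction. No library was a copy of another one in its group by a chi-square comparison of counts. CPM are counts scaled by library total and TMM factor to a common total. For Xist the library total alone was used, and embryos with Xist under 10 CPM on that scale were taken as male.

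Genes were tested in R 4.3.3 with edgeR 4.0.16, using filterByExpr by group, TMM factors, robust dispersions and the quasi-likelihood F test, on all 7 libraries, with 15800 genes kept. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05 and two-sided tests. The fit chosen before the data were examined had group as its only term, and a fit with the date code as a further term (a replicate block) was planned beside it. Because the fit with group only called 0 genes in every comparison, the rule for naming genes was also applied to the fit with the date block, a decision made after the data were seen. The 4 comparisons were TAF10KO against WT, TAF10HET against WT, TAF10KO against TAF10HET, and TAF10KO against the mean of the other 2 groups; they share libraries and are not independent. Genes were named by a rule. Taf10 and Epor were named in every comparison. Up to 6 genes with the largest rise and 6 with the largest fall were named per pairwise comparison, among called genes with a mean log2 CPM of at least 1 and the same direction on both date codes, or with no overlap between groups for the comparisons with TAF10HET; sex-linked, pseudogene and predicted symbols were left out. From each gene list, the 2 called members with the smallest adjusted p were named for TAF10KO against WT, or the most abundant member where none was called. Other genes named beside these were chosen after their values were seen. Log2 CPM used a prior count of 2. The SE of a fitted log2 fold change is its absolute value divided by the square root of its quasi-likelihood F statistic. That of a difference in CPM comes from the spread between libraries.

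There were 33 gene lists, fixed before the data were examined, for erythroid genes, subunits of TFIID, SAGA and ATAC, stress and cell-cycle programs and markers of other liver and blood cells. A list of 6 sex-linked genes served only to check embryo sex, and 32 lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 32 lists. The same test with a correlation estimated per list and fry were run as alternatives. Bcl2l1 stands in the lists of erythropoietin response and of apoptosis. Hbb-b1, Hbb-b2 and Ahsp were absent from the files under these symbols. Alternatives for each comparison were median-of-ratios and upper-quartile factors, DESeq2 1.42.0, no filter on low counts, a filter of 5 CPM in 2 libraries, globin genes left out of library totals, the date block, only the groups compared, non-robust dispersions, and each library left out in turn. The same alternatives on the fit with the date block, and embryo sex as a further term, were added after the data were seen.

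The procedure was tested on simulated data with 15800 genes and this layout of groups and date codes. For TAF10KO against WT, edgeR with group only recovered 7% of 100 genes changed 2-fold and 57% of 100 genes changed 4-fold, with 0 false calls among 64. With the date block it recovered 81% and 100%, and 26 of its 207 calls (12.6%) were false, above the nominal 5%. For TAF10KO against TAF10HET the date block gave 27 false calls of 212 (12.7%), and with DESeq2 these shares were 13.6% and 16.9%. For TAF10HET against WT, where 0 genes were changed, the date block gave 2 calls with edgeR and 3 with DESeq2, all of them false. A single data set was simulated, with genes drawn independently and dispersions taken from the fit of these data with the date block. The changed genes were drawn only from well-counted genes, so recovery of genes with low counts was not measured. The false shares depend on the number and size of the changes put in, so they cannot be carried over to the real calls. EdgeR with group only called 64 genes for TAF10KO against WT in the simulation and 0 in the real data. Figures were drawn in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.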

Results

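The polyadenylated RNA of 7 single fetal livers at stage E12.5 was compared between 3 genotypes. Taf10 encodes a subunit of TFIID, the general factor that recruits RNA polymerase II to promoters, and of the SAGA coactivator complex. The 2 TAF10KO embryos carried lox-flanked Taf10 alleles and EpoCre, a Cre recombinase driven from the erythropoietin receptor gene, which is active in erythroid cells. Their sample titles give both alleles as lox, whereas the series text gives a lox allele over a knockout allele. Of the 3 TAF10HET embryos, all with EpoCre, replicate 1 carried a lox and a wild-type allele, and replicates 2 and 3 a wild-type and a knockout allele. The 2 WT embryos had both alleles lox-flanked and no Cre. The reads assigned to genes numbered 33421125 and 43401474 in TAF10KO replicates 1 and 2. They numbered 19784658, 27280055 and 18008391 in TAF10HET replicates 1 to 3, and 25248620 and 22821489 in WT replicates 1 and 2. TAF10HET replicate 1 and TAF10KO replicate 2 were male, with Xist at 2.58 and 1.41 CPM, and the other 5 libraries had Xist at 1609 to 2148 CPM.

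Libraries separated by date code before genotype. The first principal component held 63.2% of the variance and placed the 3 libraries of the first date code between -71.2 and -46.7 and the 4 of the second between 23.2 and 52.95. The second component held 11.5%. The biological coefficient of variation was 33.9% with group as the only term and 13.4% with the date code as a block. Each comparison below therefore gives the number of genes called with group only beside that with the date block, and "rose" and "fell" refer to an adjusted p under 0.05 with the date block.

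**Figure D1:**
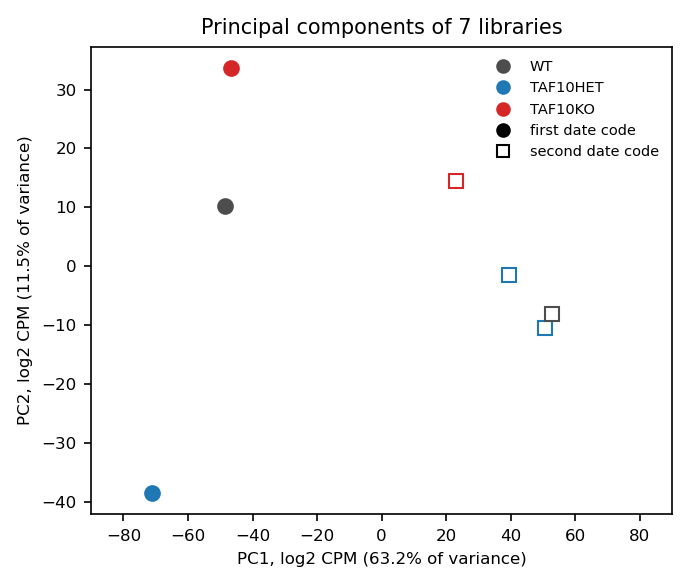
Scores of the 7 libraries on the first 2 principal components of log2 CPM, which hold 63.2% and 11.5% of the variance, with 1 point per library, coloured by genotype and shaped by date code. Libraries of the first date code lie between -71.2 and -46.7 on the first component, and those of the second between 23.2 and 52.95.

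Taf10 (ENSMUSG00000043866, chromosome 7, 105739393 to 105744361) was present in every library. It stood at 37.8 and 43.8 CPM in TAF10KO replicates 1 and 2, at 78.1, 63.7 and 63.0 CPM in TAF10HET replicates 1 to 3, and at 72.0 and 96.5 CPM in WT replicates 1 and 2. The counts include exons outside any deleted part, and liver cells without the Cre keep their lox alleles undeleted, so this level does not measure the extent of deletion. The log2 difference of TAF10KO from WT was -1.04 (SE 0.189, adjusted p = 0.88) with group only and -1.04 (SE 0.168, adjusted p = 0.0542) with the date block, and within the 2 date codes it was -0.93 and -1.14. The block gave -0.31 for TAF10HET against WT (adjusted p = 0.999) and -0.73 for TAF10KO against TAF10HET (adjusted p = 0.0782). The TAF10HET values pool unlike alleles. On the first date code the liver with a lox and a wild-type allele (78.1 CPM) lay above WT (72.0). On the second, the livers with a wild-type and a knockout allele (63.7 and 63.0) lay below WT (96.5). Allele type in TAF10HET cannot be told apart from date code. Leaving out 1 library moved the difference of TAF10HET from WT to -0.028 without WT replicate 2, -0.53 without WT replicate 1 and -0.56 without TAF10HET replicate 1. That of TAF10KO from TAF10HET moved to -0.48 (adjusted p = 0.0234) without TAF10HET replicate 1, and it passed the threshold there, with DESeq2 (0.00116), with no filter (3.38e-10) and with embryo sex as a term (0.0162). For TAF10KO against WT, DESeq2 passed the threshold with group only (-1.05, adjusted p = 0.00526) and with the block (4.06e-06). The block in edgeR passed it with only the groups compared (4.75e-05) and without TAF10HET replicate 1 (0.000269). It also passed with no filter (5.37e-18) and with embryo sex as a term (0.00724). Without WT replicate 2 the difference was -0.77. With no filter it was -0.997, close to the value under the filter. The far smaller adjusted p there rests on the estimate of spread and not on a larger difference. Only the groups compared and embryo sex as a term leave less information on the spread. The p-values of these settings are not read as stronger evidence.

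Epor (ENSMUSG00000006235, chromosome 9, 21958897 to 21963506), the erythropoietin receptor gene that the Cre driver is named for, averaged 91.2 ± 11.4 CPM in TAF10KO (SD, n = 2), 140.3 ± 15.5 in TAF10HET (n = 3) and 198 ± 56.9 in WT (n = 2). The log2 difference of TAF10KO from WT was -1.12 with group only and -1.11 with the date block (adjusted p = 0.0618), with -0.93 and -1.27 within the date codes. TAF10KO and TAF10HET carry EpoCre, driven from this gene, and WT does not. An effect of the driver on Epor therefore cannot be told from one of Taf10 loss in comparisons with WT. The difference of TAF10HET from WT was -0.50 with group only (adjusted p = 1), and that of TAF10KO from TAF10HET was -0.61 with the block (adjusted p = 0.15). With the block, the difference of TAF10HET from WT was -0.50 (adjusted p = 0.999), and it was -0.16 without WT replicate 2, -0.78 without WT replicate 1 and -0.77 without TAF10HET replicate 1; it passed the threshold with no filter (1.25e-05). That of TAF10KO from TAF10HET was -0.33 without TAF10HET replicate 1, and it passed with DESeq2 (0.0196) and with no filter (1.45e-07). For TAF10KO against WT, DESeq2 passed the threshold with group only (-1.13, adjusted p = 0.00818) and with the block (1.73e-06). The block in edgeR passed it with only the groups compared (5.68e-05), with no filter (1e-22) and without TAF10HET replicate 1 (0.000964). Without WT replicate 2 the difference was -0.78. With no filter it was -1.07, so the far smaller adjusted p there rests on the estimate of spread and is not read as stronger evidence.

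**Figure D2:**
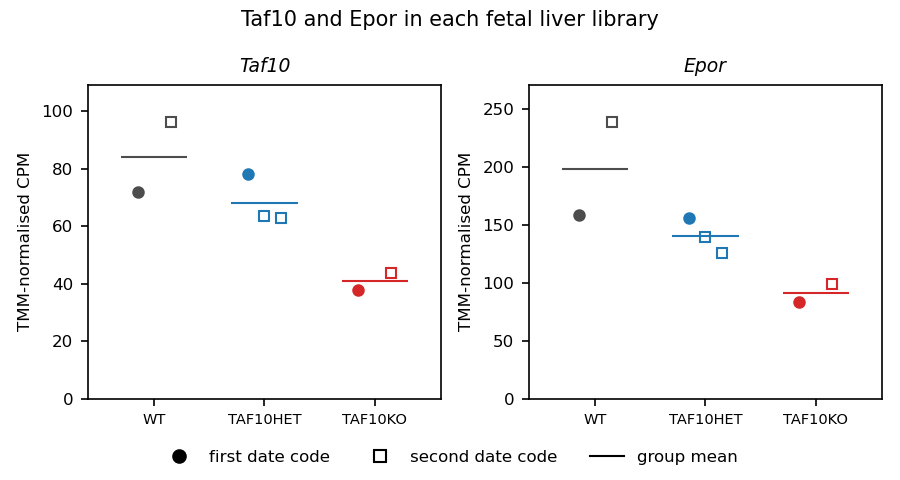
TMM-normalised CPM of Taf10 and Epor in the 7 libraries, with 1 point per library, shaped by date code, and a line at the mean of each genotype (n = 2 for WT, 3 for TAF10HET and 2 for TAF10KO). Taf10 lies at 37.8 and 43.8 CPM in TAF10KO and at 63.0 to 96.5 CPM in the other libraries.

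Between TAF10KO and WT, genes of hypoxia and glycolysis rose together. These groups differ in EpoCre as well as in the Taf10 deletion intended in erythroid cells, so this comparison cannot tell them apart. The glycolytic enzymes Aldoa and Pgk1 rose from 497 ± 147 to 1319 ± 371 CPM (log2 1.41, SE 0.105, adjusted p = 0.00458) and from 452 ± 42.2 to 988 ± 107 CPM (SD, n = 2 each). Bnip3, a mitophagy receptor (log2 1.49), Egln3, an oxygen-sensing prolyl hydroxylase (2.00), and Vegfa, the vascular growth factor (1.27), also rose. Of the 16 genes of the list, 10 rose and 0 fell over all genes tested, and 15 rose and 0 fell adjusted over the list alone. Among those that missed the threshold over all genes, Adm stood at 1.32 (adjusted p = 0.148), Slc2a1 at 0.39 (0.263) and Car9 at 0.24 (0.775). The list's median was 1.02, with 0.97 and 1.06 within the date codes. On both date codes 15 of 16 members were higher. Camera gave adjusted p = 5.27e-47, and adjusted p = 0.0178 with an estimated correlation; fry gave 0.00164. With group only these were 7.95e-28, 0.15 with an estimated correlation and 0.134 by fry. The number of members that rose was 0 without WT replicate 1 or WT replicate 2 and 5 without TAF10HET replicate 3, and the median stayed between 0.90 and 1.101 over the leave-outs.

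Outside that list, the largest rise among the genes named by the rule was in Ndufa4l2 (ENSMUSG00000040280, chromosome 10, 127514967 to 127517154), a mitochondrial protein gene induced by low oxygen, from 3.24 ± 2.31 to 28.5 ± 18.8 CPM (n = 2 each; log2 3.18, SE 0.176, adjusted p = 0.00314), with 3.19 and 3.08 within the date codes. Igfbp1, an insulin-like growth factor binding protein, rose from 35.3 ± 5.07 to 149.9 ± 3.51 CPM (log2 2.10, SE 0.182, adjusted p = 0.00894). Without WT replicate 1 the adjusted p was 0.0653 for Ndufa4l2 and 0.219 for Igfbp1, and without WT replicate 2 it was 0.104 and 0.269. The others with the largest rises were Slc7a3, a cationic amino acid transporter (3.13), Stc2, stanniocalcin (2.63), Slc7a11, a cystine transporter (2.10), and, from the hypoxia list, Ankrd37 (2.03). In the list of the integrated stress response, to which Slc7a11 and Sesn2 (0.93) belong, 2 of 13 genes rose and 0 fell. Adjusted over the list alone 7 rose and 1 fell. Its median was 0.90, with 0.42 and 1.06 within the date codes (camera adjusted p = 4.35e-08, but adjusted p = 0.467 with an estimated correlation). Its uncalled members Trib3 and Ddit4 stood at 2.44 and 2.21. Immediate-early and heat-shock genes, which respond to handling of tissue, had a median of 0.60 (0.47 and 0.71 within the date codes; camera adjusted p = 4.01e-05, but adjusted p = 0.248 with an estimated correlation). Over all genes 0 of 11 were called, and 6 were higher adjusted over the list alone. Dusp1, the most abundant member, stood at -0.26.

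Among the embryonic globins, 2 of 3 genes fell. Hbb-y, the embryonic beta-like globin, fell from 2419 ± 683 to 1209 ± 194 CPM (n = 2 each; log2 -0.98, adjusted p = 0.030), with -0.85 and -1.11 within the date codes. Hba-x, the embryonic zeta globin, fell from 560 ± 343 to 133 ± 28.1 CPM (log2 -1.90, adjusted p = 0.04996), and Hbb-bh1 stood at -0.43 (adjusted p = 0.138). Hba-x lost its call without WT replicate 1 (adjusted p = 0.322), WT replicate 2 (0.637), TAF10HET replicate 2 (0.107) or TAF10HET replicate 3 (0.139), with globin genes out of the library totals (0.0501) and with non-robust dispersions (0.0514). Adjusted over the list alone all 3 fell. The median of -0.98 gave camera adjusted p = 4.35e-08 but adjusted p = 0.248 with an estimated correlation. With group only the list's median was -1.001, and it shrank to -0.857 without TAF10KO replicate 1 and to -0.677 without WT replicate 2. Adult globins had a median of -0.19 over 4 genes (adjusted p = 0.183), with Hbb-bs at -0.52 (adjusted p = 0.223), and 0 were called.

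Other erythroid lists had medians closer to 0 than the embryonic globins. Late erythroid maturation genes had a median of -0.21 over 15 genes (camera adjusted p = 0.0493, but adjusted p = 0.609 with an estimated correlation). Over all genes 0 were called, and 2 were higher and 5 lower adjusted over the list alone. Car2, a carbonic anhydrase, stood at -0.58 (adjusted p = 0.0698). Red cell membrane genes had a median of -0.20 over 17 (adjusted p = 0.00471, but adjusted p = 0.609 with an estimated correlation). Slc4a1, the anion exchanger of that membrane, stood at -0.29. Haem synthesis genes had a median of -0.16 over 13 (adjusted p = 0.0279, but adjusted p = 0.624 with an estimated correlation). Slc25a37, the mitochondrial iron importer, stood at -0.06. Both of these lists had 0 called genes over all genes and 0 higher and 2 lower adjusted over the list alone. Without TAF10KO replicate 2 the adjusted p became 0.995 for the membrane list and 0.941 for the haem list, and the haem list gave 0.0619 without WT replicate 1. The maturation list lost its call without TAF10KO replicate 1 (0.182), TAF10KO replicate 2 (0.183), TAF10HET replicate 1 (0.0844) or WT replicate 1 (0.277). With group only the maturation list gave 0.0613 and the haem list 0.0754. Erythroid transcription factors had a median of -0.024 and a mean of 0.007 over 14 genes (adjusted p = 0.869), with Tal1 at -0.12 and 1 gene higher adjusted over the list alone. Their median passed in opposite directions without TAF10KO replicate 1 (-0.218, adjusted p = 0.0128) and without TAF10KO replicate 2 (0.123, adjusted p = 0.0159). Among iron genes, the transferrin receptor Tfrc fell from 2463 ± 245 to 1378 ± 139 CPM (log2 -0.84, adjusted p = 0.0438) and the ferritin light chain Ftl1 rose (1.02, adjusted p = 0.041). The median of the 11 iron genes was -0.08 (adjusted p = 0.53), and -0.192 without TAF10KO replicate 1 (0.0469). Erfe, the erythroferrone hormone that erythroblasts secrete under erythropoietin, rose by 0.83 on the log2 scale (adjusted p = 0.04996). Its adjusted p was 0.0511 with median-of-ratios factors, 0.0501 with upper-quartile factors, 0.0501 with globin genes out of the library totals and 0.0629 with non-robust dispersions, which also gave 0.0595 for Tfrc and 0.055 for Ftl1. The list of erythropoietin response had a median of 0.22 over 9 genes (adjusted p = 0.0472, but adjusted p = 0.503 with an estimated correlation). In it 1 gene rose over all genes and 2 adjusted over the list alone, and Pim1 stood at 0.10. Its call ended without TAF10KO replicate 1 (0.154), TAF10KO replicate 2 (0.115), WT replicate 1 (0.0913), TAF10HET replicate 2 (0.0539) or TAF10HET replicate 3 (0.051), and with group only (0.137).

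Markers of other cell types also differed. The endothelial list had a median of 0.52 over 12 genes, with 0.51 and 0.58 within the date codes (camera adjusted p = 2.43e-08, but adjusted p = 0.404 with an estimated correlation). Flt1, a receptor for vascular growth factor (log2 1.18, adjusted p = 0.0244), and Pecam1 (0.64, adjusted p = 0.0438) rose, and adjusted over the list alone 9 rose and 1 fell. The neutrophil list had a median of 0.68 over 12 (0.46 and 0.84 within the date codes; adjusted p = 3.18e-07, but adjusted p = 0.503 with an estimated correlation). None of its genes was called over all genes, and 5 were higher adjusted over the list alone. The macrophage list had a median of -0.44 over 13 (-0.33 and -0.52; adjusted p = 1.75e-06, but adjusted p = 0.543 with an estimated correlation). It had 0 called genes over all genes and 4 lower adjusted over the list alone, with Vcam1 at -0.43. Megakaryocyte genes had a median of 0.27 over 14 (adjusted p = 0.00318, but adjusted p = 0.609 with an estimated correlation), with Itga2b at 0.44 and 3 higher adjusted over the list alone. Its call ended without WT replicate 2 (0.574) and without TAF10KO replicate 2 (0.124). Hepatocyte genes had a median of -0.21 over 17 (adjusted p = 0.00814, but adjusted p = 0.609 with an estimated correlation), with 1 higher and 1 lower adjusted over the list alone. They gave 0.247 without WT replicate 2, 0.495 without TAF10KO replicate 2 and 0.0547 with group only. Mesenchymal genes had a median of 0.55 over 12 (adjusted p = 0.0153, but adjusted p = 0.621 with an estimated correlation), with Col3a1 at 0.58. Without TAF10KO replicate 2 their median was -0.06 (adjusted p = 0.25), and with group only it was 0.24 (adjusted p = 0.549). The mast cell list, with a median of -0.10 and a mean of 0.02 over 3 genes (0.636), the lymphoid list (0.45 over 3, 0.53) and the cardiac list (0.59 over 4, 0.327) missed the threshold. Without WT replicate 2 the cardiac list passed (1.11, adjusted p = 0.00316).

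In the cell cycle lists, Ccne2, cyclin E of the start of S phase, fell by 0.73 on the log2 scale (adjusted p = 0.0204). The median of 18 replication genes was -0.20 (-0.04 and -0.42 within the date codes; adjusted p = 2.7e-06, but adjusted p = 0.609 with an estimated correlation). Of these 1 fell over all genes and 4 adjusted over the list alone. Without TAF10KO replicate 2 the median was -0.065 (0.183). Mitosis genes had a median of -0.10 over 16 (adjusted p = 0.0245, but adjusted p = 0.609 with an estimated correlation), with Mki67 at -0.23. They gave 0.0607 without WT replicate 1 and 0.532 without TAF10KO replicate 2. Genes of the mitochondrial genome had a median of -0.48 over 12 (-0.52 and -0.39 within the date codes; adjusted p = 4.79e-07, but adjusted p = 0.503 with an estimated correlation). Over all genes 0 were called, and 8 were lower adjusted over the list alone. Apoptosis regulators had a median of -0.16 over 14 (adjusted p = 0.0477, but adjusted p = 0.503 with an estimated correlation), with Mcl1 at -0.33 and 1 higher and 2 lower adjusted over the list alone. Their call ended without TAF10KO replicate 1 (0.182), TAF10KO replicate 2 (0.0948), TAF10HET replicate 1 (0.0589) or WT replicate 1 (0.184), and with group only (0.0943).

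The lists of subunits of TFIID and of SAGA and the related ATAC complex did not pass the test. TFIID subunits had a median of -0.05 over 15 genes (adjusted p = 0.215), with Taf1 at -0.001 and 1 gene lower adjusted over the list alone. SAGA and ATAC subunits had a median of 0.005 over 27 (adjusted p = 0.709), with Sf3b3 at -0.06. Targets of p53, which responds to DNA damage, had a median of 0.10 over 23 (adjusted p = 0.0681), with Rps27l at -0.16 and 2 genes higher adjusted over the list alone. They passed without TAF10KO replicate 1 (0.00218), TAF10HET replicate 1 (0.0489) or TAF10HET replicate 3 (0.0409). Stem and progenitor genes stood at a median of 0.19 (adjusted p = 0.0534) and cholesterol synthesis genes at 0.13 (adjusted p = 0.0577). Both passed without WT replicate 1 (0.0195 and 0.0141), and the cholesterol list also without TAF10HET replicate 1 (0.0409) or TAF10KO replicate 2 (0.00642). CDK inhibitors had a median of -0.04 and a mean of 0.20 over 5 genes (adjusted p = 0.392). Ribosomal protein genes (0.05, adjusted p = 0.901) and interferon response genes (0.05, adjusted p = 0.869) missed it as well.

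**Figure D3:**
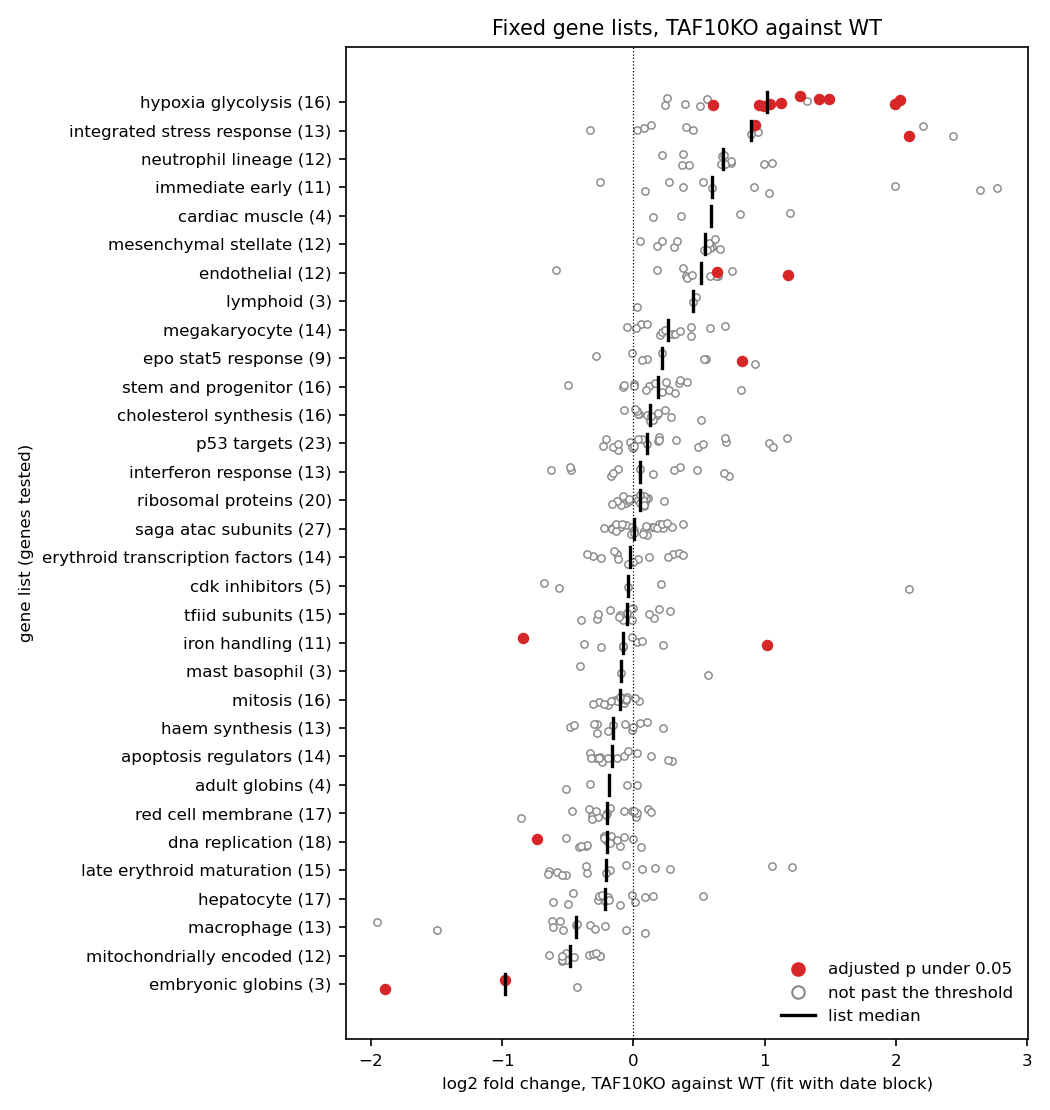
Log2 fold change between TAF10KO and WT with the date block of each tested gene of the 32 gene lists (points, filled where the adjusted p is under 0.05), with a bar at each list's median. The hypoxia and glycolysis list has the highest median (1.02) and the embryonic globins the lowest (-0.98).

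Among the other genes with the largest falls, Hsd3b6 (ENSMUSG00000027869, chromosome 3, 98805504 to 98814443), a hydroxysteroid dehydrogenase gene, fell from 34.4 ± 16.4 to 7.18 ± 2.74 CPM (n = 2 each; log2 -2.24, SE 0.137, adjusted p = 0.00334), with -2.11 and -2.33 within the date codes. The homeobox gene Lmx1a fell by 1.83 on the log2 scale, the sorting nexin Snx22 by 1.20, and Lect2, a secreted hepatocyte protein, by 1.15. With the date block edgeR called 96 genes, 76 higher and 20 lower in TAF10KO. All 96 had the same direction on both date codes. The fit was made on the same libraries and favours genes with like differences on both dates, so this is no independent support. With group only edgeR called 0, with 729 at an unadjusted p under 0.05 and a smallest adjusted p of 0.714. DESeq2 with group only called 64 (43 higher, 21 lower). Camera called 18 of 32 lists with the block, 8 higher and 10 lower, and 1 with an estimated correlation. The number of genes called with the block was 0 without WT replicate 1 or WT replicate 2, 31 without TAF10HET replicate 2 and 13 without TAF10HET replicate 3. It was 529 without TAF10KO replicate 2, 887 without TAF10HET replicate 1 and 1282 without TAF10KO replicate 1. Of the 22 called genes followed through the alternatives in this comparison, 22 lost the call without WT replicate 1, 22 without WT replicate 2, 13 without TAF10HET replicate 2, 17 without TAF10HET replicate 3 and 10 with non-robust dispersions, which called 53 genes. In simulated data 12.6% of the 207 calls of this fit were false. That share depends on the number and size of the changes put in, so it cannot be carried over to the 96 calls here.

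**Figure D4:**
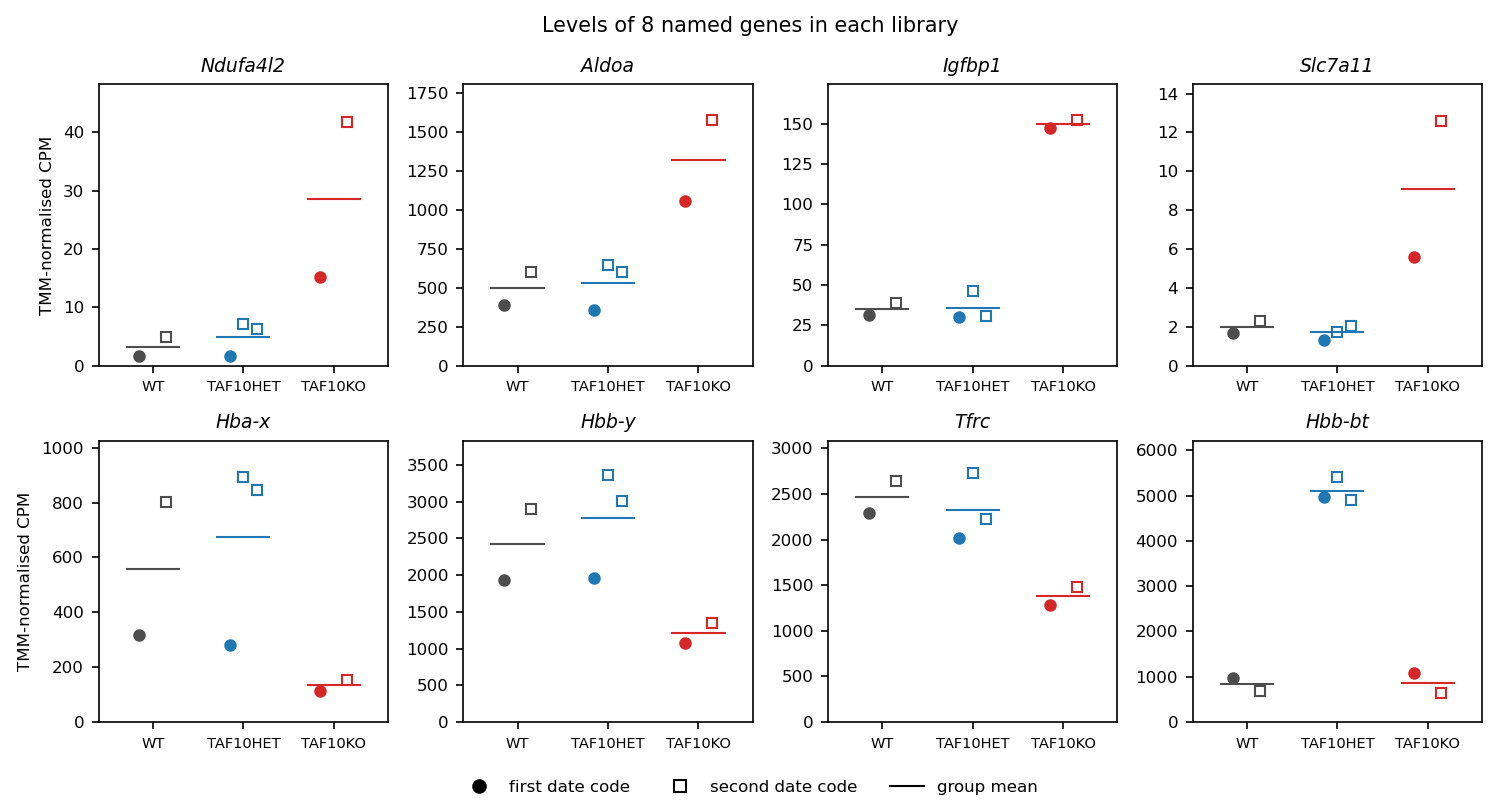
TMM-normalised CPM of 8 named genes, with 1 point per library, coloured by genotype and shaped by date code, and a line at the mean of each genotype (n = 2 for WT, 3 for TAF10HET and 2 for TAF10KO). Ndufa4l2 averages 28.5 CPM in TAF10KO and 3.24 in WT, and Hbb-bt averages 5098 CPM in TAF10HET and 830.4 in WT.

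Between TAF10HET and WT, the adult beta globin gene Hbb-bt was the single gene called. This compares livers with a deleted or deletable Taf10 allele beside a wild-type allele with undeleted livers. The groups also differ in EpoCre, which TAF10HET carries and WT does not. Hbb-bt (ENSMUSG00000073940, chromosome 7, 103812524 to 103813996) stood at 830.4 ± 194 CPM in WT (n = 2) and 5098 ± 272 CPM in TAF10HET (n = 3), and at 854.4 ± 308 CPM in TAF10KO (n = 2). It rose with the date block (log2 2.71, SE 0.198, adjusted p = 0.0245); with group only the difference was 2.62 (adjusted p = 1), and DESeq2 with the block gave adjusted p = 7.05e-57. Counts of Hbb-bt exclude reads that also aligned to its near-identical neighbour Hbb-bs. Adult globins had a median of 0.32 over 4 genes, with 1 risen over all genes and 2 adjusted over the list alone (camera adjusted p = 2.51e-11, but adjusted p = 0.171 with an estimated correlation). Hepatocyte genes had a median of -0.18 (adjusted p = 7.74e-06, but adjusted p = 0.822 with an estimated correlation), and hypoxia genes had a median of -0.035 (adjusted p = 0.118). Mesenchymal (0.34), embryonic globin (0.11) and interferon genes (0.25) also passed camera, with adjusted p = 0.881, 0.757 and 0.846 with an estimated correlation. With group only the mesenchymal median was 0.14 (adjusted p = 0.91), and late maturation (0.20, adjusted p = 0.00825) and erythropoietin response genes (0.24, adjusted p = 0.0104) passed, against 0.114 and 0.0539 with the block, but both gave adjusted p = 0.936 with an estimated correlation and 0.991 by fry. The fit with group only called 0 genes by edgeR, with 96 at an unadjusted p under 0.05, and 3 by DESeq2; the block gave 1, with 530 unadjusted. In simulated data with 0 genes changed in this comparison, the block also called 2 genes, both of them false. Hbb-bt lost its call without WT replicate 1 (adjusted p = 0.245), WT replicate 2 (0.663) or TAF10HET replicate 3 (0.299), and with non-robust dispersions (0.0531). The count was 13 without TAF10KO replicate 1 or 2, 8 without TAF10HET replicate 1 and 2 without WT replicate 1.

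Between TAF10KO and TAF10HET, both with EpoCre, hypoxia and glycolysis genes rose, 11 of 16 over all genes and 14 adjusted over the list alone. Their median was 1.06 (adjusted p = 1.84e-63, and adjusted p = 0.0113 with an estimated correlation). Aldoa rose by 1.44 on the log2 scale (adjusted p = 0.0016) and Ndufa4l2 by 2.82 (adjusted p = 0.00125). The other largest rises were those of Slc7a3 (2.57), Stc2 (2.51), Slc7a11 (2.47), the stress protein gene Nupr1 (2.14) and Igfbp1 (2.11). All 3 embryonic globins fell, Hba-x by 1.96, Hbb-bh1 by 1.26 and Hbb-y by 1.08 (list adjusted p = 2.45e-15, but adjusted p = 0.0877 with an estimated correlation). Against WT, Hbb-bh1 was not called. Other large falls were those of Hbb-bt (-2.68), Hsd3b6 (-2.30), Lmx1a (-1.97), the axonemal chaperone gene Dnajb13 (-1.68) and the calcium channel gene Cacna1g (-1.55). In Hbb-bt TAF10KO differed from WT by only 0.025 (log2, SE 0.191), so its fall here reflects the high level in TAF10HET. TAF10KO and TAF10HET also differ in their Taf10 chromosomes. For genes near Taf10 on chromosome 7, where Hbb-bt and Hbb-bh2 lie, a linked segment cannot be told from Taf10 loss.

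Adult globins had 2 of 4 genes fallen, Hbb-bt and Hba-a2 (-0.65, adjusted p = 0.0373), with a median of -0.50 (adjusted p = 4.19e-08, but adjusted p = 0.106 with an estimated correlation). Hbb-bt counts toward this list result although TAF10KO stood close to WT in it (log2 0.025, SE 0.191). In late erythroid maturation Bpgm, Car2, Ube2l6 and Xpo7 fell and Car1 rose by 1.09 on the log2 scale (list adjusted p = 0.00159, but adjusted p = 0.555 with an estimated correlation). Integrated stress response genes had a median of 0.72 with 3 of 13 risen (adjusted p = 5.68e-11, but adjusted p = 0.327 with an estimated correlation). Beside these, neutrophil genes had a median of 0.70, with the granule protein genes Mpo (0.80) and Prtn3 (0.74) risen (adjusted p = 5.68e-11, but adjusted p = 0.40 with an estimated correlation). Endothelial genes had a median of 0.46 with 4 risen (adjusted p = 8.5e-08, but adjusted p = 0.327 with an estimated correlation). Macrophage genes had a median of -0.61, with C1qa fallen and 10 lower adjusted over the list alone (adjusted p = 3.44e-10, but adjusted p = 0.411 with an estimated correlation). Megakaryocyte genes had a median of 0.41 with 0 called over all genes (adjusted p = 2.55e-06, but adjusted p = 0.437 with an estimated correlation).

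Camera called 18 of 32 lists between TAF10KO and TAF10HET with the block, 8 higher and 10 lower, with 1 called with an estimated correlation and 4 by fry. With group only these were 17, 0 and 2. The other lower lists were mitochondrially encoded genes (median -0.33, adjusted p = 4.57e-05), replication (-0.16, 0.000142), red cell membrane (-0.19, 0.00584), haem synthesis (-0.18, 0.0227), interferon response (-0.38, 0.0301) and apoptosis regulators (-0.165, 0.0351). The other higher lists were immediate-early and heat-shock genes (0.58, 0.000142), cholesterol synthesis (0.14, 0.0201) and stem and progenitor genes (0.21, 0.0372). Each of these 9 lists gave an adjusted p of at least 0.19 with an estimated correlation. With group only the interferon (0.0803) and stem cell lists (0.206) missed the threshold and the mitosis list passed it (-0.10, 0.023).

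With the block 254 genes were called between TAF10KO and TAF10HET, 182 higher and 72 lower. With group only edgeR called 0, with 854 at an unadjusted p under 0.05, and DESeq2 called 98. The count with the block was 26 without WT replicate 1 or WT replicate 2, 42 without TAF10HET replicate 2, and 16 without TAF10HET replicate 3. It was 486 without TAF10HET replicate 1. In simulated data 12.7% of such calls were false, a share that depends on the changes put in and cannot be carried over to these calls. Of the 12 called genes followed through the alternatives, 7 lost the call without WT replicate 1, 7 without WT replicate 2, 8 without TAF10HET replicate 3, 4 without TAF10HET replicate 2, 2 without TAF10KO replicate 2, 1 without TAF10HET replicate 1 and 7 with only the groups compared.

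Against the mean of WT and TAF10HET, Taf10 fell by 0.89 on the log2 scale in TAF10KO (adjusted p = 0.0299) and Epor by 0.86 (adjusted p = 0.0475), both with the date block. The block called 457 genes, 316 higher and 141 lower, and 17 lists by camera, 1 of them with an estimated correlation. With group only edgeR called 0, with 1017 at an unadjusted p under 0.05 and a smallest adjusted p of 0.191, and DESeq2 called 152. The count with the block was 16 without WT replicate 1, 20 without WT replicate 2, 149 without TAF10HET replicate 2 and 40 without TAF10HET replicate 3. It was 1228 without TAF10HET replicate 1, 787 without TAF10KO replicate 2 and 1585 without TAF10KO replicate 1.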

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

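No tests were run on the results in this part, so none was chosen after the data were seen. Some genes named as the most abundant member of a list without called genes differed between TAF10KO and WT in opposite directions on the 2 date codes, with 1 library per group on each, and the difference between the dates was not tested. The log2 differences on the first and the second date code were 0.115 and -0.26 for Slc25a37, the mitochondrial iron importer, 0.029 and -0.286 for Tal1, an erythroid transcription factor, and 0.07 and -0.077 for Taf1, the largest TFIID subunit. They were 0.033 and -0.16 for Sf3b3, a subunit of SAGA and of the spliceosome, -0.383 and 0.058 for Rps27l, a p53 target, and -0.16 and 0.057 for Cdkn1c, a CDK inhibitor. The values were 0.132 and -0.334 for the fetal hepatocyte protein Afp, -0.011 and 0.714 for the neutrophil gene S100a9, and -0.522 and 0.558 for the B cell gene Cd79b. With the date block none of these 9 genes was called between TAF10KO and WT.

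Some classes of reads outside the gene counts were more frequent in some libraries than in the WT control libraries, by more than the WT libraries differed from each other. Reads in no annotated gene made up 10.1% of all reads counted in TAF10HET replicate 1, 9.09% in TAF10HET replicate 3 and 8.005% in TAF10KO replicate 2, against 6.81% and 7.23% in WT replicates 1 and 2. They made up 7.36% in TAF10KO replicate 1 and 7.34% in TAF10HET replicate 2, above both WT libraries by less than that difference. Reads ambiguous between genes made up 5.94% in TAF10HET replicate 2, against 4.83% and 3.98% in WT, and 5.53% in TAF10KO replicate 1. Reads aligned to several places, the most frequent class, were highest in WT replicate 2 (22.25%), with 17.5% in WT replicate 1 and 14.1% to 21.8% in the other 5 libraries.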

How the results depend on the processing

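The alternatives run on the fit with the date block, and the tests with embryo sex as a term, were chosen after the data were seen; the others were chosen before the data were examined. With group only, edgeR called 0 genes in TAF10KO against WT, TAF10HET against WT, TAF10KO against TAF10HET and TAF10KO against the mean of both (729, 96, 854 and 1017 at an unadjusted p under 0.05), and stayed at 0 under each alternative and leave-out except these. The date code as replicate block gave 96, 1, 254 and 457 genes, DESeq2 gave 64, 3, 98 and 152, and no filter on low counts gave 1 in the third comparison and 8 in the fourth. Taf10 and Epor passed in TAF10KO against WT by DESeq2 alone among those alternatives, at -1.05 and -1.13.

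With the replicate block, DESeq2 called 566, 14, 665 and 926 genes, no filter 1399, 289, 1498 and 1906, and embryo sex as a further term 2725, 32, 2743 and 3445. With no filter the Taf10 and Epor differences in the first comparison stayed at -0.997 and -1.069 while their adjusted p fell far. The sex term leaves less information on the spread. The higher counts of these settings are not read as more evidence of change. Only the groups compared gave 553, 7 and 26 and was not run for the fourth comparison, which uses every library. Non-robust dispersions gave 53 in the first comparison and 0 in the second. The factors, the stricter filter and the globin genes left the counts within 1.5 times. Leaving out 1 library gave 0 to 1282, 0 to 13, 16 to 1203 and 16 to 1585 genes. The lowest counts in the first comparison were without WT replicate 1 or WT replicate 2, 0 in both, and the highest without TAF10KO replicate 1; leaving a group with 1 library assumes that it varies like the others. Apart from the smaller number of libraries, the cause was not tested.

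For TAF10KO against WT, camera called 12 lists with group only, 0 with an estimated correlation and 0 by fry. With the block it called 18, 1 with an estimated correlation and 1 by fry, and 10 to 18 when 1 library was left out, the lowest without TAF10KO replicate 2. Of the 32 list medians, 18 with group only and 10 with the block took the other sign without at least 1 library, and the cause was not tested. With group only the widest of these ranges were those of mesenchymal (-1.015 to 1.959), mast cell (-0.415 to 0.723) and cardiac genes (-0.103 to 0.967) and of CDK inhibitors (-0.525 to 0.202). Where camera turned in direction with a call before or after, the lists with group only were red cell membrane (-0.487 to 0.122 over the leave-outs, the highest without WT replicate 2), erythroid transcription factors (-0.336 to 0.311, the highest without WT replicate 2) and ribosomal proteins (-0.118 without TAF10KO replicate 2, to 0.19). With the block they were erythroid transcription factors (-0.218 without TAF10KO replicate 1, 0.123 without TAF10KO replicate 2) and mesenchymal genes (-0.060 without TAF10KO replicate 2, to 1.05). Over all alternatives with the block, values of named genes kept direction and side of the threshold 901 times, lost the threshold 129 times, gained it 62 times, turned in direction with no call 25 times and with a call 0 times; for lists, by the direction of camera, these were 271, 57, 10, 12 and 2. With group only they were 934, 0, 57, 30 and 0 for genes and 288, 35, 37, 21 and 3 for lists. The scaling alternatives moved the median of all genes by -0.006, 0 and 0. Depth was 18008391 to 43401474 counts per library, and genes under the filter were not tested.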

Other observations

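Of the tests in this part, those of thinned counts, of choices of libraries within date codes and of the chromosome segment around Taf10 were set before their results were seen, and the other tests after. Gene groups also differed between the date codes. With group and date code in 1 fit, edgeR called 6536 of 15800 genes between the 4 libraries of the second date code and the 3 of the first, 2956 higher and 3580 lower. All 12 mesenchymal genes fell (median log2 -2.43, second minus first), and 11 of 12 endothelial genes were called (median -0.89), with 14 of 17 hepatocyte genes (median -0.50, camera adjusted p = 0.000397) and 8 of 13 macrophage genes (-0.66, 0.000942). The stromal genes Col14a1 (-2.55), Abcc9 (-2.22) and Colec10 (-2.52), chosen after their values were seen, fell. Several erythroid lists had higher medians on the second date: 13 of 14 transcription factors were called (median 0.64), 16 of 17 red cell membrane genes (0.59), 13 of 13 haem synthesis genes (0.53), 10 of 15 late maturation genes (0.45, 6.83e-05) and all 3 embryonic globins (0.97). Adult globins (1 of 4 called, 0.20, adjusted p = 0.431) and iron genes (6 of 11, 0.28, adjusted p = 0.104) missed the threshold of camera. Hypoxia and glycolysis genes (12 of 16 called, median 0.37, camera adjusted p = 0.00819), replication (10 of 18, 0.32, 0.00105), neutrophil (5 of 12, 0.37, 0.0151) and integrated stress response genes (6 of 13, 0.39, 0.0158) also had higher medians on the second date. Mitosis (0.22) and ribosomal protein genes (0.18) did too (0.0137 each), and cholesterol synthesis had a lower one (-0.35, 0.00555). Camera gave adjusted p = 8.15e-20 for the mesenchymal list, 1.25e-07 for the endothelial list and for the transcription factors, 2.22e-06 for the membrane list, 3.05e-05 for haem synthesis and 0.00503 for the embryonic globins, but every list in this paragraph gave adjusted p = 0.544 with an estimated correlation.

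TAF10HET replicate 1 stood apart in genes of heart muscle. Actc1, cardiac actin, stood at 49.1 CPM there and at 1.79 to 3.11 CPM in the other 6 libraries, and Tnnt2, cardiac troponin, at 8.43 CPM against 0.0928 to 1.55. The median of the 4 tested cardiac genes in this library was 2.69 above the WT mean on the log2 scale. The same library had 15.6% of its counts in its 10 most abundant genes, against 6.85% to 9.02% in the others, with Gm42418, a noncoding transcript, at 78950 CPM against 2203 to 19140.

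For hypoxia and glycolysis genes, higher in TAF10KO than in WT, every library was thinned to the smallest total, 18008391 counts. The list's median was then 0.991 and 10 of 16 members passed, with 89 genes called, 79 of them among the 96. Thinning leaves the expected fold change of well-counted genes unchanged, so this median cannot decide on deeper sequencing of the TAF10KO libraries. The counts show only that most calls were also made at equal depth. The marker lists of the 6 other cell types with at least 10 tested markers had lower means than the hypoxia list (1.01). The highest was 0.639 for neutrophil genes (one-sided permutation tests over genes, adjusted p of at most 0.0216). These tests took genes as units and were set after the hypoxia list stood out as the highest. They therefore do not measure the spread between livers, and more cells of another type stay open as a cause. Erythroid lists were not part of them. The 4 heart muscle genes, at a mean of 0.63, were not separated by that test (adjusted p = 0.114). The heart muscle list was higher by only 1.78 CPM in all (SE 3.41), against 3400 CPM (SE 1080) for the hypoxia list. Handling or dissociation stress of the TAF10KO livers may contribute and cannot be told apart from genotype, since immediate-early and heat-shock genes had a median of 0.597 with adjusted p = 0.248 with an estimated correlation, and no record of handling is in the labels. A lower oxygen supply, or an effect of Taf10 loss in erythroid cells, stays open and was not tested. In a fit with the date block and all other libraries pooled as 1 group, 12 choices of 1 library per date code were compared. The real choice, TAF10KO, gave 729 genes, and the highest other choice, the pair of male libraries, gave 35. The comparison with the mean of WT and TAF10HET is a different fit and called 457. With 12 choices the smallest share is 0.083, too few for a share under 0.05.

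Hbb-bt was higher in TAF10HET (5098 ± 272 CPM, n = 3) than in the 4 lox_lox libraries of WT and TAF10KO (842.4 ± 211 CPM). The number of functional Taf10 copies as its cause is argued against, since TAF10KO differed from WT by 0.025 (log2, SE 0.191) in this gene. A candidate explanation is a linked segment around Taf10 that differs between the lox chromosome and the wild-type chromosome. TAF10HET replicate 1 carries a lox chromosome beside the wild-type one, and replicates 2 and 3 a knockout chromosome, whose segment is not known. Hbb-bt stood at 4967, 5411 and 4915 CPM in replicates 1 to 3. Within 10 Mb, 18 of 166 genes (10.8%) had no overlap between TAF10HET and lox_lox libraries, against 417 of 15634 elsewhere (2.67%; chance gives 5.71%). The odds ratio was 4.44 (95% interval 2.53 to 7.35; Fisher's exact test, two-sided, p = 7.59e-07). Hbb-bt, the gene to be explained, is among the 18, and neighbouring genes are not independent, so this p-value overstates the evidence. The 18 genes included Trim30d (3.10), Trim5 (2.70), Hbb-bh2 (1.72) and Trim12a (0.93), higher in TAF10HET. Gm15506 (-1.25), Gm4759 (-0.70) and Pde3b (-0.18) were the 3 that were lower. Whether expression differs or reads of another strain map differently was not tested. Reads moved between Hbb-bt and its near-identical copy Hbb-bs stay open, as Hbb-bs differed by 501.7 CPM with an SE of 3456 CPM. That SE ignores the date code and includes the spread between dates. On the first date code Hbb-bs stood at 14380 CPM in TAF10HET, 8907 in TAF10KO and 13030 in WT. On the second it stood at 18360 and 16280 CPM in TAF10HET, 17240 in TAF10KO and 24180 in WT.

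The date codes separated the libraries. A different share of stromal cells in the suspensions may account for part of this, since the mesenchymal list differed by a median of -2.428, with 12 of 12 genes called; hepatocyte, macrophage and endothelial lists were lower too, so a wider shift in cell composition stays open. Reads assigned differently to processed pseudogenes stay open. Pseudogenes made up 1.09% of the 6536 genes called (71 genes), but only 455 pseudogenes were tested. Their share of the calls was therefore bound to be small and cannot decide this, and changes in their parent genes were not counted. Pseudogenes were more frequent among the genes with a difference over 3 on the log2 scale, 10 of 90 (odds ratio 4.29, Fisher's exact test, two-sided, p = 0.000259). The dates were not linked to a developmental or a library batch in the labels, and other explanations were not tested.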
